A study of Arabidopsis thaliana with 8 samples.

How the data were processed

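Transcript levels were measured in shoots of Arabidopsis thaliana (ecotype Col-0) with 8 one-colour ATH1 microarrays, an array type whose probe sets each read 1 transcript or a group of related transcripts. Biotin-labelled target was made from total RNA, per the labels. Wild-type seedlings and seedlings with a T-DNA insertion in HSA32 (AT4G21320), a gene for a heat-stress-associated protein, were kept for 2 h at 22 °C (control) or 37 °C (heat) at an age of 15 days. Each of the 4 groups held 2 biological replicates, and each replicate was a separate pool of plants, per the series design. Groups and replicate numbers were taken from the sample titles. The source description of wild-type control replicate 1 names heat without the word control, whereas its title names it a control, and the title was followed.

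The authors deposited 1 intensity value per probe set and array, on a linear scale and never negative. The software, the algorithm and the settings behind these values are not given in the sources used here. The values themselves show a scaling to a 2% trimmed mean of about 500 on every array, from 500.04 to 500.07. No detection calls were used, so signal over background could be judged only from the level of a value. The number of arrays limits the precision of every comparison.

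The deposited values were used with their scaling, since the trimmed means lay within 5% of each other. Of 22810 probe sets, 64 controls and the dimmest 30% by mean signal over all arrays (61.7 or lower) were left out, which left 15919 tested. Values were analysed as log2(signal + 29), where 29 is the 20th percentile of all deposited values. A fold change on this scale understates changes of dim transcripts. A mean per group was fitted in limma 3.58.1 (R 4.3.3), with a variance trend and without robust moderation. The fit had 4 residual degrees of freedom and 4.79 prior ones. The 5 contrasts were heat against control in each genotype, knockout against wild type at each temperature, and their interaction, which tests whether the heat response differed between genotypes. All tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Errors of fold changes are standard errors from limma, and errors of signals are standard deviations.

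Gene names came from the platform annotation supplied with the data. It paired 13513 probe sets with 1 gene and 503 with several, and 8730 further probe sets, controls aside, were unnamed here. Among the tested probe sets 8790 had 1 gene, and only these were named. Symbols were updated through a RefSeq gene table, in which 77 of the gene numbers were not found. Where several probe sets read 1 locus, the brightest stood for it in the gene lists, and 90 loci had more than 1 tested probe set. The genome build behind the annotation was not given, so genes are given by locus and without coordinates.

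Before the data were examined, 24 gene lists with 352 loci were fixed. They covered small heat shock proteins, the HSP70, HSP90 and HSP100 families, chaperonins, cochaperones, heat shock factors, other heat response genes, ER protein folding, the proteasome, dehydration and abscisic acid, light harvesting and Rubisco, chlorophyll synthesis, the cell cycle, DNA replication, reactive oxygen, jasmonate, salicylate and defence, auxin, the circadian clock, flavonoids, cell wall loosening, and markers of root, seed and flower. Of these loci 60 had a named probe set and 56 were tested. HSP90 and HSP100, heat shock factors, jasmonate, seed and flower had no member with a named probe set, so these 5 lists gave no result. Each of the 9 lists with at least 3 tested members was tested with camera at a preset inter-gene correlation of 0.01, against all other tested probe sets. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it. A further 14 lists were formed after the data had been seen, from genes that the annotation named. Adjustment over a list alone is given beside adjustment over all probe sets tested.

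The genes named were chosen by a rule written before the data were examined. For each contrast it took the 10 highest and the 10 lowest fold changes among the genes that passed, provided that the arrays of the groups compared did not overlap, except in the interaction. It added HSA32, up to 4 members of each fixed list with the smallest adjusted p, and any list member that passed between genotypes. Where no gene passed in a direction, the 3 smallest p-values were given as not passing. Genes outside this rule are named in the report only as members of the fixed lists and in the closing part as members of the added lists, and they were chosen after their values were seen. Loci among the 10 on either side of HSA32 were tested as a separate set.

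The alternatives set before the data were examined were pseudocounts of 7.25 and 116, no filter or a filter on the dimmest 50%, quantile normalization, centring of each array on its median, no variance trend, the replicate number as a block, only the 4 arrays compared, and each array left out in turn. A block that crosses the replicate numbers (also with an estimated correlation for the lists) and a fit without both arrays of wild-type replicate 1 were added after the data had been seen. The procedure was tested on simulated data with 15919 probe sets and the spread of the real arrays. Only a small share of the probe sets was changed in each simulation, and noise was drawn independently for each array. The real arrays deviated together in sets and the real heat contrasts held more changes. The rates below need not hold for them. Of simulated 4-fold changes it called 32.2% for heat in wild type, 21.6% for heat in the knockout, 26.1% between genotypes at 22 °C and 23.9% after heat. Of 8-fold changes it called 72.9%, 71.6%, 70.4% and 48.4%, in the same order. It called 0% of 8-fold interactions, although their median estimate was 3.01 on the log2 scale. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.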

Results

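Shoot transcript levels were compared between wild-type Arabidopsis and a T-DNA knockout of HSA32, with and without 2 h at 37 °C. HSA32 (AT4G21320) encodes a heat-stress-associated protein known for its part in long-term acquired thermotolerance. Each combination of genotype and temperature had 2 arrays, each from its own pool of plants, which makes 8 arrays. The deposited signals reached 21808 to 57211 on single arrays, with medians from 131 to 181. Replicates correlated across probe sets, which are not independent, at 0.922 in wild-type controls, 0.87 in heated wild type, 0.944 in knockout controls and 0.949 in the heated knockout. The first principal component held 60.1% of the variance and parted heated from control arrays. The second held 22.0% and set the arrays of wild-type replicate 1 (46.5 for control and 67.8 for heat) apart from the other 6, which lay at 12.5 or lower.

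HSA32 itself rose after heat in wild type and had no such rise in the knockout. Its signal was 657 and 230.0 in the wild-type controls and 23175 and 9240 after heat, which is 444 ± 302 against 16208 ± 9853 (SD, n = 2). In the knockout it was 1125 and 1247 at 22 °C (1186 ± 86.2, SD, n = 2) and 378 and 589 after heat (484 ± 149, SD, n = 2). Heat raised HSA32 in wild type by 5.12 ± 0.57 on the log2 scale (adjusted p = 0.0016), a 34.8-fold change. In the knockout its heat log2 fold change was -1.27 ± 0.57 and did not pass (adjusted p = 0.22). After heat the knockout lay at -4.87 ± 0.57 relative to wild type, and the interaction was -6.39 ± 0.80. Each had the smallest p of all probe sets in its contrast (1.5e-05 and 2.6e-05), yet neither passed over all probe sets (adjusted p = 0.23 and 0.42). With a block that crosses the replicate numbers, chosen after the data had been seen, both passed over all probe sets (adjusted p = 0.0051 and 0.0094). That block was picked from the residuals of these same arrays, so its smaller error is partly built in. Without both arrays of wild-type replicate 1 the values were -4.21 after heat and -6.44 in the interaction. Adjusted over the 5 contrasts of this gene alone, the fit without a block gave 3.7e-05 and 4.4e-05. At 22 °C HSA32 lay 1.52 ± 0.57 above wild type, with adjusted p = 1 over all probe sets and 0.032 over this gene's contrasts. That last call was lost without wild-type control replicate 2, knockout control replicate 1 or knockout control replicate 2. Where the probe set lies relative to the insertion is not given in the sources used here, so the signal that stayed in the knockout does not check the labels on its own.

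**Figure D1:**
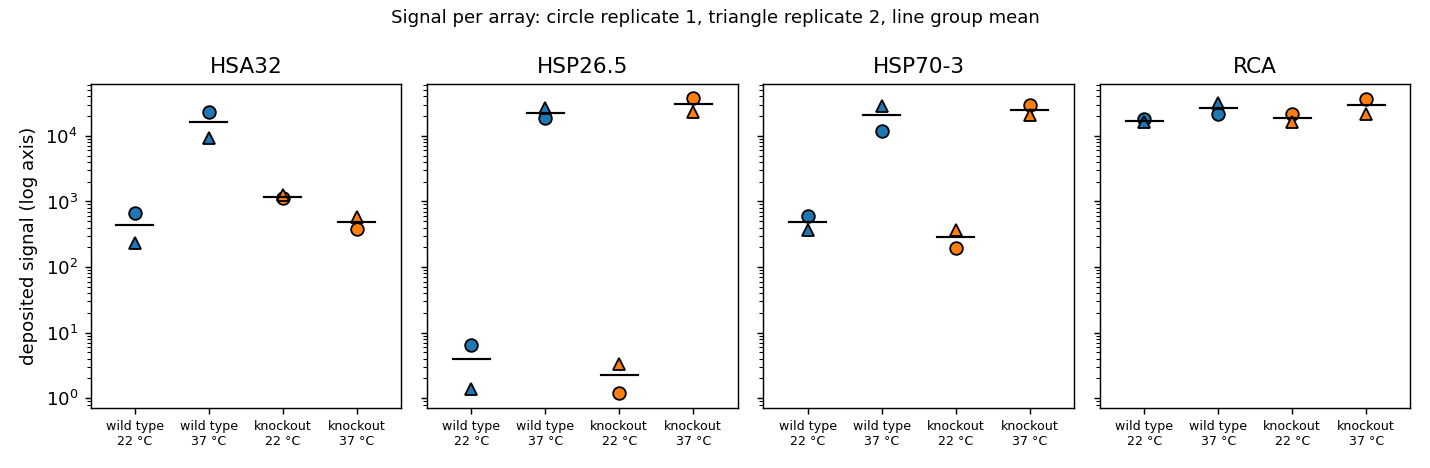
Deposited signal (log axis) of HSA32, HSP26.5, HSP70-3 and RCA on each of the 8 arrays, with wild type in blue, the knockout in orange, replicate 1 as circles, replicate 2 as triangles and the group mean as a line. HSA32 reached 16208 on average in heated wild type and 484 in the heated knockout, whereas HSP26.5 reached 22516 and 30229.

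What heat did to wild-type shoots was asked first. Small heat shock proteins, which hold unfolding proteins in solution, were among the named genes with the highest changes. HSP26.5 (AT1G52560) rose by 9.40 ± 0.37 on the log2 scale (adjusted p = 1.1e-05, n = 2), from a mean signal of 3.90 to 22516. ATHSP22.0, HSP23.5-M, HSP17.6B-CI, HSP17.6C-CI and HSP15.7 rose by 7.55 to 8.36, and the peptidyl-prolyl isomerase ROF2 by 7.97 ± 0.43. The other rises among the 10 highest of the named genes were AT1G71000 at 7.64, the J-domain protein gene DNAJ (AT2G20560) at 6.88 and AT1G72660 at 6.87. Probe sets not paired with 1 gene were left out of this ranking, and some of them rose more than most of these genes. In the fit with the crossed block, such probe sets had rises of 9.26, 8.94 and 8.74 in wild type. Mean control signals of HSP26.5, AT1G71000 and AT1G72660 lay under the offset of 29, so the size and rank of their folds depend on it. Among genes that fell, GAT1_2.1 (AT1G15040), named for a glutamine amidotransferase domain, changed by -3.67 ± 0.61 (adjusted p = 0.015) and AT4G28240 by -3.29 ± 0.68 (adjusted p = 0.042). AT1G13000 changed by -2.72 ± 0.36 (adjusted p = 0.0047) and AT2G28200 by -2.53 ± 0.30 (adjusted p = 0.0023). AT5G57760, AT1G25400, AT2G19660, the brassinosteroid-responsive RING gene BRH1, AT1G06760 and AT1G71970 fell as well, by values from -2.59 to -2.43.

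The fixed lists gave the following counts in wild type. Among small heat shock proteins 7 of 8 rose (median 7.85), also when adjusted over the list alone, and HSP15.4 did not pass at -1.12. In the HSP70 family, chaperones that bind unfolded segments, HSP70-3 rose by 5.22 ± 0.50 and Hsp70-2 by 3.59 ± 0.60, while HSP70-16 (2.07) and HSP70-17 (1.66) did not pass; adjusted over the list alone, 4 of 4 passed. Of 7 cochaperones 5 rose, on either adjustment, among them Hop3 (6.70) and Hop2 (3.63), which link HSP70 to HSP90, and Fes1A (5.62), a nucleotide exchange factor of HSP70. Hop1 (-0.06) and P23-1 (0.56) did not pass. The chloroplast chaperonin gene Cpn60beta2, 1 tested of its list, rose by 4.98 ± 0.61, and BZIP28, a transcription factor of the ER stress response and 1 tested among other heat response genes, by 1.82 ± 0.37. The dehydrin gene COR47 rose by 1.85 ± 0.34, as 1 of 4 in the dehydration and abscisic acid list, on either adjustment.

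Camera placed small heat shock proteins (adjusted p = 5.2e-23), cochaperones (1.3e-13), the HSP70 family (2.7e-07) and dehydration and abscisic acid genes (0.011) above other genes in heated wild type. With an estimated correlation the first 3 lists had adjusted p = 0.044 each, but 0.076 each with the crossed block, where the calls were lost, and the dehydration list had adjusted p = 0.33 with an estimated correlation. Fry called the first 3 lists (adjusted p = 0.00022, 0.0018 and 0.0045, in the order given) but not the dehydration list (0.2). That list also lost its call without wild-type control replicate 1 and without wild-type heat replicate 2. None of 4 genes passed for ER protein folding (median -0.22), of 4 for light harvesting and Rubisco (0.40) or of 4 for chlorophyll synthesis (-0.15), with camera adjusted p = 0.77, 0.067 and 0.84. Light harvesting and Rubisco was called with the crossed block (adjusted p = 0.037, and 0.48 with an estimated correlation). It was also called without wild-type heat replicate 1, knockout heat replicate 1, knockout heat replicate 2 or both arrays of wild-type replicate 1, and the last of these also called cell wall loosening. No gene passed among 3 auxin genes (median -0.70, camera adjusted p = 0.88) or 6 cell wall loosening genes (-1.17, 0.44). In the lists with 1 or 2 tested genes, the proteasome genes RPN2A (0.34) and RPN12a (-0.02), the cell cycle kinases AUR1 (-0.17) and AUR2 (0.20) and the replication gene PRL (-0.12) did not pass. Nor did STZ for reactive oxygen (1.82 ± 1.04), SAG101 for salicylate and defence (-0.39), GI for the clock (-0.28) or DFR for flavonoids (0.33). None of these genes passed when adjusted over its list alone.

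In all, 406 of 15919 probe sets passed in limma in wild type, 293 higher and 113 lower, and 188 of them had 1 gene (141 higher, 47 lower). The median log2 fold change of all probe sets was -0.22, and centring each array moved it to 0.03 and the split to 355 higher and 52 lower. The count was 160 without wild-type control replicate 2 (151 higher, 9 lower), 1314 without wild-type heat replicate 1 (473 higher, 841 lower), 878 without both arrays of wild-type replicate 1 (393 higher, 485 lower) and 1406 with the crossed block (589 higher, 817 lower). Which direction held more calls was therefore not settled. Of the 10 named genes that fell, 9 lost the call without wild-type control replicate 2, while the 10 that rose kept theirs with any array left out.

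The same question was put to the knockout. Heat raised HSP26.5 by 9.88 ± 0.37 on the log2 scale (adjusted p = 7.2e-06, n = 2), from 2.25 to 30229. DNAJ rose by 8.96 ± 0.61, HSP17.6B-CI by 8.74 ± 0.36, AT1G71000 by 8.71, AT1G21550 by 8.60, HSP17.6C-CI and ROF2 by 8.55 each, HSP23.5-M by 8.47, HSP15.7 by 8.37 and AT5G07330 by 8.07. Mean control signals of HSP26.5, DNAJ, AT1G71000, AT1G21550 and AT5G07330 lay under the offset of 29 here, so these folds depend on it. The ring-finger gene ATL8 (AT1G76410) fell, at -4.55 ± 0.79 (adjusted p = 0.013), followed by GAT1_2.1 at -4.18 ± 0.61 (adjusted p = 0.0057). AT5G57760 (-3.59), AT4G28240 (-3.46), BRH1 (-3.37), AT4G01330 (-3.20), AT5G50180 (-3.05), AT1G19380 (-3.01) and AT2G28200 (-2.98) fell, as did COB (-3.02), which encodes an anchored protein of oriented cell expansion.

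By list, 7 of 8 small heat shock proteins rose in the knockout (median 8.42), with HSP15.4 at -1.65 not passing over all probe sets and lower when adjusted over the list alone. The HSP70 family rose in 4 of 4 genes, also when adjusted over the list alone, with HSP70-3 at 6.37 ± 0.50, Hsp70-2 at 4.34, HSP70-16 at 2.71 and HSP70-17 at 2.48. Cochaperones rose in 5 of 7 on either adjustment, with Hop3 at 7.89, Fes1A at 6.52 and Hop2 at 4.19, and Hop1 (0.22) and P23-1 (0.55) did not pass. Cpn60beta2 rose by 5.94 ± 0.61, BZIP28 by 2.41 ± 0.37 and COR47 by 1.5 ± 0.34. The expansin gene EXPA4, whose product loosens cell walls, fell at -2.73 ± 0.66 (adjusted p = 0.044), as 1 of 6 cell wall loosening genes on either adjustment. Its wild-type value of -2.14 did not pass (adjusted p = 0.14), and its interaction of -0.59 did not pass either. In the auxin list 0 of 3 passed over all probe sets and 2 were lower when adjusted over the list alone, WES1 (-1.65) and IAA29 (-1.53). The EXPA4 call was lost at nearly the same size under quantile normalization (-2.55 ± 0.71, adjusted p = 0.077) and median centring (-2.42 ± 0.65, adjusted p = 0.07). Under quantile normalization COR47 missed the threshold at 1.51 ± 0.34 in wild type (adjusted p = 0.06) and shrank to 0.96 ± 0.34 in the knockout (adjusted p = 0.15).

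Camera called small heat shock proteins (adjusted p = 2.4e-18), cochaperones (2.3e-12) and the HSP70 family (2.6e-07) in the heated knockout, and each had adjusted p = 0.052 with an estimated correlation (0.092 with the crossed block). Fry called the same 3 lists (adjusted p = 0.00017, 0.00094 and 0.0018, in that order). Dehydration genes (median 0.20), light harvesting and Rubisco (0.35), chlorophyll synthesis (0.05), ER protein folding (-0.13), cell wall loosening (-1.65) and auxin genes (-1.53) had camera adjusted p from 0.14 to 0.67. Under quantile normalization 3 of these medians changed sign, light harvesting to -0.23, chlorophyll synthesis to -0.09 and ER protein folding to 0.12, so no direction is given for them. RPN2A (-0.14), RPN12a (-0.09), AUR1 (-0.27), AUR2 (0.17), PRL (0.00), STZ (1.28), SAG101 (-0.45), GI (0.27) and DFR (0.06) did not pass.

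Limma passed 1080 probe sets for heat in the knockout, 498 higher and 582 lower, of which 532 had 1 gene (253 higher, 279 lower). The split became 580 higher and 355 lower under quantile normalization and 616 higher and 226 lower under median centring, against a median of -0.26 for all probe sets as deposited. Leaving out 1 array gave 230 (knockout control replicate 1), 240 (knockout control replicate 2), 279 (knockout heat replicate 1), 280 (knockout heat replicate 2), 1996 (wild-type heat replicate 2) and 2000 (wild-type heat replicate 1). Without a knockout array the calls higher made up 75.0% (knockout heat replicate 2) to 88.7% (knockout control replicate 1) of the calls, and 36.9% were higher without wild-type heat replicate 1 (738 higher, 1262 lower). Of the 10 named genes that fell, 9 lost the call without knockout heat replicate 2, and 0 of the 10 that rose lost theirs with any array left out.

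**Figure D2:**
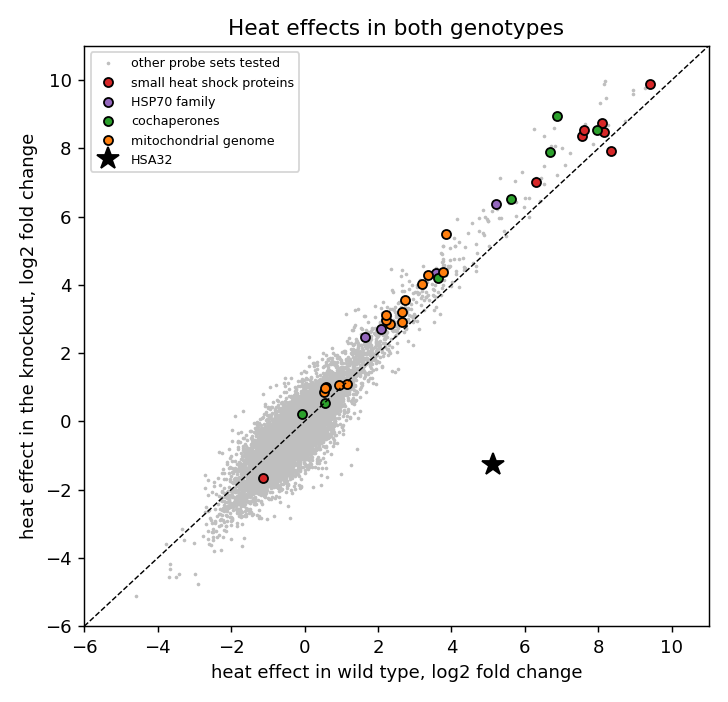
Log2 fold change after heat in the knockout (vertical) against wild type (horizontal) for each tested probe set, with members of 4 gene groups in colour, HSA32 as a star and equality as a dashed line. Small heat shock proteins, HSP70 genes and cochaperones lie along the line up to 9.40 in wild type, while HSA32 lies at 5.12 in wild type and -1.27 in the knockout.

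Whether the heat response of the knockout as a whole had the size of the wild-type response was then examined. Of the probe sets called in wild type 386 were also called in the knockout, with 288 higher in both (9.17 for independent lists) and 98 lower in both (4.13 for independent lists). None was called in opposite directions, and 405 of 406 wild-type calls and 1077 of 1080 knockout calls had the same sign in the other genotype. The 2 fold changes share no array, but both calls use the same estimate of the spread of a probe set. The numbers called in both can exceed those for independent lists for that reason too. Over all tested probe sets the slope of knockout on wild-type fold changes was 1.07, with Pearson r of 0.907 and Spearman rho of 0.818. Pairings of single replicates gave an SD of 0.0811, but they reuse the same arrays, so it is not an error of this slope. Over the 21 probe sets of the heat lists the slope was 1.11 with r of 0.988. These values run across genes, which are not independent replicates. The slope lay under 1 without wild-type control replicate 1 (0.964), wild-type control replicate 2 (0.919), wild-type heat replicate 1 (0.783) or wild-type heat replicate 2 (0.930). It was 0.844 without both arrays of wild-type replicate 1. Noise in the wild-type fold changes lowers such a slope, and leaving out wild-type arrays adds noise. These slopes therefore cannot tell which genotype had the larger response, and that was not settled.

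At 22 °C no gene was found to differ between the genotypes. Limma passed 0 of 15919 probe sets (82 at an unadjusted p under 0.05, fewer than a uniform spread of p would give). The smallest p-values with the knockout higher belonged to AT3G22850 (1.4 ± 0.36), AT1G27040 (1.56 ± 0.43) and AT5G53880 (1.28 ± 0.37). With the knockout lower they belonged to AT2G05600 (-1.63 ± 0.45), AT5G20560 (-1.24 ± 0.34) and AT3G10020 (-1.20 ± 0.37), all with adjusted p = 1. None of the fixed list members passed, also when adjusted over its list alone. Cochaperones were lower by camera (median -0.31, adjusted p = 0.0072) and dehydration and abscisic acid genes higher (median 0.46, adjusted p = 0.01), with DNAJ at -1.65 ± 0.61 and COR15A at 0.69 ± 0.38. Each had adjusted p = 0.34 with an estimated correlation, fry called 0 lists, and 0 lists were called without wild-type control replicate 1 or without knockout control replicate 1, against 4 without wild-type control replicate 2. Of the 21 heat list transcripts 19 were higher in wild-type control replicate 1 than in replicate 2, and 14 were higher in knockout control replicate 2 than in replicate 1. HSP70-3 read 596 and 372 in the wild-type controls and 196 and 370 in the knockout controls, by replicate, whereas COR47 read 3543 and 6518 in the wild-type controls.

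After heat, the probe set with the smallest p between the genotypes was that of HSA32. Limma passed 0 probe sets here too, against 280 (1.76%) at an unadjusted p under 0.05. That is also fewer than a uniform spread of p would give, and the crossed block had 783. The absence of calls therefore does not show that no gene differed. In heated shoots AT3G22850 had 1.65 ± 0.36, AT5G39090 1.85 and the thionin gene THI2.1 1.35 ± 0.40 with the knockout higher. AT5G13520 (-1.64 ± 0.34) and AT1G14950 (-1.58 ± 0.35) lay lower, and HSA32 lay at -4.87. AT3G22850 read 718 to 1333 on the 4 knockout arrays and 282 to 341 on the 4 wild-type arrays, so the genotypes did not overlap at either temperature, though the gene passed at neither. All 8 small heat shock proteins had positive values (median 0.23), as had 4 of 4 HSP70 genes (0.41) and 7 of 7 cochaperones (0.27), with camera adjusted p of 0.12, 0.18 and 0.26. ER protein folding genes were higher by camera (median 0.50, adjusted p = 0.04), with ATERDJ3B at 0.90 and CNX2 at 0.69, none of which passed on either adjustment. That list had adjusted p = 0.81 with an estimated correlation, fry called 0 lists, and the list was not called without any of the 4 control arrays, the 2 heated wild-type arrays or knockout heat replicate 2.

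The interaction asked which heat responses differed between the genotypes. HSA32 had the smallest p here, at -6.39 ± 0.80. Limma passed 0 probe sets, with 88 (0.55%) at an unadjusted p under 0.05 and 239 with the crossed block. Both counts are again fewer than a uniform spread of p would give. Other small p-values belonged to AT5G20560 (1.48), AT2G34400 (1.97) and AT2G07732 (2.00) on the higher side and to AT1G14950 (-2.02 ± 0.49) and AT3G45720 (-2.15) on the lower side. By camera the response was larger in the knockout for cochaperones (median difference 0.58, adjusted p = 0.00054), the HSP70 family (0.79, 0.0089) and small heat shock proteins (0.56, 0.011). It was more negative for auxin genes (-0.96, 0.017), whose heat medians were -0.70 in wild type and -1.53 in the knockout. With an estimated correlation the adjusted p was 0.28 for cochaperones, the HSP70 family and auxin genes and 0.41 for small heat shock proteins, and fry called 0 lists. None of their members passed on either adjustment, with DNAJ at 2.08 and HSP70-3 at 1.14. The lists called fell from 4 to 0 without wild-type control replicate 1 and to 0 without wild-type heat replicate 1, and to 2 without knockout control replicate 1 or knockout heat replicate 2.

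Neighbours of HSA32 and markers of other tissues were checked last. Of 20 loci beside HSA32, 7 had a named probe set and 2 were tested, AT4G21310 and AT4G21323. Neither passed between genotypes over all probe sets or when adjusted over the list alone (smallest adjusted p = 0.16), with values from -0.91 to 1.62. The root marker EXPA18, the only tested member of the tissue markers fixed in advance, had -0.61 ± 0.49 after heat in wild type and -0.44 ± 0.49 in the knockout and passed in neither.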

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

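The sets of arrays, the tests of scaling, transcript length and loss toward the 5' end on them, the tests of heated RNA and of a wrong label, the crossed block and the fit without wild-type replicate 1 were chosen only after the result was seen; the bound for scaling was written before its value was computed, and quantile normalization and the single arrays left out were set before.

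HSA32 differed in its heat response between the genotypes, by -6.39 on the log2 scale, which is the design's own contrast. Without a block it did not pass over all probe sets after heat or in the interaction (limma adjusted p = 0.23 and 0.42). With the crossed block it was the 1 probe set that passed in both. That block was picked from the residuals of these same arrays, so its smaller error is partly built in. Without both arrays of wild-type replicate 1 the values of HSA32 were -4.21 and -6.44. Camera set the heat response of the knockout apart for cochaperones (adjusted p = 0.00054), the HSP70 family (0.0089), small heat shock proteins (0.011) and auxin genes (0.017). With an estimated correlation none of these 4 was called, at 0.28 to 0.41.

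The 8 arrays fell into 2 sets that cross the groups, wild-type replicate 1 with knockout replicate 2 and wild-type replicate 2 with knockout replicate 1. The 5S ribosomal RNA control probe set read 20 and 24.1 in wild-type replicate 1 and 14.8 and 43.5 in knockout replicate 2, against 550 and 770 in wild-type replicate 2 and 1360 and 1086 in knockout replicate 1. The 25S control did not follow these sets: it read 14840 to 20677 in wild type, 385, 850 and 1363 on 3 knockout arrays and 13530 in knockout heat replicate 2. The sets, picked because the residuals fell that way, took 54.2% of the residual variance as deposited and 52.3% after quantile normalization, which argues against scaling between arrays. A split fixed in advance would be expected to take 25%, as 1 of 4 residual degrees of freedom, and a split picked from the residuals tends to take more. Loss toward the 5' end stays open: the higher 3' to 5' ratio lay with the wild-type replicate 1 set in 3 of the 4 groups, and the heated knockout differed the other way by -0.04 ± 0.11 (SE over 3 control genes). The older control probe sets also gave 3 of 4, with the knockout controls the other way (-0.29 ± 0.12). Transcript length stays open because only 54.9% of tested probe sets had a gene span (rho of 0.36 in wild type and 0.45 in the knockout among those), a processing batch or day may also lie behind the sets, no label gives one, and no biological explanation was tested.

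Most of the strongest heat-induced transcripts lay above replicate 2 in wild-type control replicate 1, whose source description names heat. This held for 35 of 39 transcripts at least 64-fold higher after heat in wild type and for 200 of the 293 called higher, but not for COR47 (3543 against 6518). In the knockout controls replicate 2, of the same set of arrays, lay above replicate 1 for 18 of the 39 and 144 of the 293, though for 14 of the 21 heat list transcripts. A wrong label, with a heated sample in place of a control, is argued against by the first principal component, which uses no labels. On it this array lay at -52.1, the other control arrays from -68.5 to -58 and the heated arrays from 33.4 to 74.5. None of the 32 transcripts above the filter value on this array exceeded 4.80% of its heated level. These were picked by a fold that counts this array as a control. Low percentages were therefore partly built in and cannot exclude a wrong label. A share of heated RNA stays open. Of these 32 transcripts 6.25% lay more than 3-fold below their median of 0.971%, too few to exclude it. Transcripts under the filter value on this array were left out as near the floor, HSP26.5 at 0.0284% of its heated level among them. The test therefore left out low readings that could go against such a share. A milder stress of that pool of plants may also account for the pattern and was not tested.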

How the results depend on the processing

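The crossed block, alone and with an estimated correlation, and the fit without both arrays of wild-type replicate 1 were tests chosen only after the result was seen. For heat in wild type, 155 probe sets passed with only the 4 arrays compared, 878 without wild-type replicate 1 and 160 to 1314 with 1 array left out. For heat in the knockout, the values were 2433, 2424 and 230 to 2000. With only 2 pairs in each comparison the replicate numbers do not pair the samples by rule: arrays of the same number deviated together within genotypes (0.54 and 0.52) and apart between them (-0.35 and -0.39). The replicate block gave 290 for wild type and 675 for the knockout. Crossing the numbers gave 1406, 2859, 1 after heat and 1 in the interaction. Without wild-type replicate 1, the counts after heat and in the interaction were also 1 each, and in all 4 cases this was HSA32. The crossed block with an estimated correlation left 0 lists in each of the 5 contrasts. Lists called for heat in the knockout went from 3 to 0 with an estimated correlation, while fry called the same 3. Between genotypes at 22 °C they went from 2 to 0 with an estimated correlation, 0 with fry and 0 without wild-type replicate 1, and ran from 0 to 4 with 1 array left out. After heat they went from 1 to 0 with no filter, an estimated correlation, fry, the crossed block and without wild-type replicate 1, and ran from 0 to 2. In the interaction they went from 4 to 0 with an estimated correlation, fry and without wild-type replicate 1, and ran from 0 to 6. The slope was 0.844 without wild-type replicate 1 and ran from 0.783 to 1.12. Fewer arrays explain part of the leave-one-out changes by construction, and a lone array in a group was assumed to vary like the other groups. Replicates differed most in heated wild type (SD of the log2 difference 0.95, against 0.56 to 0.67 in the other groups), and all groups shared 1 estimate of the spread. Leaving out 1 array of heated wild type, or comparing only the 4 knockout arrays, took that difference out of the estimate. Calls for heat in the knockout then rose, although its fold changes stayed the same. For the other changes the cause was not tested. HSA32 after heat ran from -5.53 to -4.21 and kept its call over its own contrasts under each alternative that fitted all 5 of them. None of the named genes that passed changed sign under an alternative, but the slope fell under 1 without each wild-type array. Several list medians changed sign, of which some are given here. Quantile normalization moved light harvesting in wild type from 0.40 to -0.11 and plastid transcripts in the knockout from 0.22 to -0.12. It also moved nuclear photosystem and NDH subunits from 0.30 to -0.19 in wild type and from 0.38 to -0.12 in the knockout. In wild type median centring moved ER folding from -0.22 to 0.04, chlorophyll synthesis from -0.15 to 0.11 and plastid transcripts from -0.22 to 0.04. Among the single named results, 5 calls were lost under quantile normalization, 5 under median centring, 10 with no filter, 11 with the replicate block and from 0 to 21 with 1 array left out. Without detection calls, signal over background limits the dim genes.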

Other observations

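The lists in this part were formed, and the tests of the mitochondrial genome pattern were chosen, only after the result was seen.

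Among transcripts of the mitochondrial genome all 15 tested had positive heat values in both genotypes, few of which passed in wild type, with medians of 2.31 in wild type and 2.98 in the knockout. In wild type 2 rose, nad5 (3.77 ± 0.68) and nad9 (2.21 ± 0.43), both subunits of respiratory complex I, and 9 when adjusted over the list alone. In the knockout 9 rose, among them nad6 (5.49), nad5 (4.38), ccb203 (4.28), cox2 (4.03) and nad9 (2.98), and 11 when adjusted over the list alone. Camera gave adjusted p = 9.5e-12 in wild type and 1.9e-12 in the knockout, but 0.88 and 0.77 with an estimated correlation, and fry did not call the list (0.45 and 0.23). A change of the group as a whole therefore rests on the preset correlation. Of 68 plastid genome transcripts, rps18 (-2.27) fell in the knockout and no other passed in either genotype, with medians of -0.22 and 0.22, the latter -0.12 under quantile normalization. Camera placed the plastid list higher after heat in the knockout (adjusted p = 0.029), but not with an estimated correlation (0.77). The rps18 call was lost under median centring at -1.96 ± 0.48 (adjusted p = 0.051), and 0 plastid transcripts passed when adjusted over the list alone. Between the genotypes after heat, camera placed both groups higher in the knockout (1e-05 for mitochondrial and 1.5e-06 for plastid transcripts), which had adjusted p = 0.81 and 0.76 with an estimated correlation. Plastid transcripts were also placed higher at 22 °C (0.016), and both groups in the interaction (0.011 and 0.037), with 0.53 and 0.88 for these with an estimated correlation. At 22 °C expansins (0.0042), xyloglucan endotransglucosylases (0.0082) and ATG8 genes (0.045) were placed higher too, and expansins lower in the interaction (0.037), all lost with an estimated correlation (0.53, and 0.88 in the interaction). Fry called 0 of these lists.

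Single genes passed in other lists. The list of other cochaperones had medians of 0.10 and 0.00. Camera called it in wild type (adjusted p = 0.013) and in the knockout (0.029), but not with an estimated correlation (0.88 and 0.77). BOB1 rose by 4.36 ± 0.41 in wild type and 5.10 in the knockout, SGT1A by 3.95 and 4.55 and SQN by 2.58 and 3.03. Fes1B (-1.62) fell in the knockout, so that 3 of 10 and 4 of 10 passed. Among 13 SWEET sugar transporters SWEET2 fell in both genotypes (-2.19 and -1.95) and SWEET1 rose in the knockout (2.02 ± 0.37). Of 27 UDP-glycosyltransferases, UGT73C1 (2.67) and UGT76E11 (2.00) rose and UGT76C1 (-1.59) fell in the knockout, and 0 passed in wild type. Of 14 expansins, EXPA9 (-1.62) and EXPA4 (-2.73) fell in the knockout, and in wild type 0 passed over all probe sets and 1 was lower when adjusted over the list alone. None of these differences between genotypes passed in the interaction. SWEET2, UGT76C1, Fes1B and EXPA4 narrowly missed the threshold under quantile normalization and median centring (adjusted p from 0.059 to 0.09), with somewhat smaller folds: SWEET2 at -2.09 ± 0.48 and -1.93 ± 0.45 in wild type, UGT76C1 at -1.36 ± 0.35 and -1.29 ± 0.34, Fes1B at -1.38 ± 0.40 and -1.31 ± 0.37 and EXPA4 at -2.55 ± 0.71 and -2.42 ± 0.65. In limma 0 passed in either genotype among 14 nuclear photosystem and NDH subunits, 9 ATG8 autophagy genes, 7 tubulins, 6 tau glutathione transferases, 6 xyloglucan endotransglucosylases, 15 trichome birefringence-like genes, 5 additional root markers and 5 pollen markers. Camera placed the nuclear photosystem and NDH subunits higher after heat in the knockout (adjusted p = 0.029), but not with an estimated correlation (0.77). Their median changed sign under quantile normalization, from 0.38 to -0.12 in the knockout and from 0.30 to -0.19 in wild type, so no direction is given.

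For the mitochondrial pattern, a scaling factor per array would move all probe sets alike and could not set the list apart from them. The list lay 2.54 above their median in wild type, a distance that centring each array does not alter. Quantile normalization can alter it, and there the list medians were 2.41 in wild type and 3.10 in the knockout. All probe sets had medians of -0.074 and -0.079 there. More organelle RNA in general would move plastid transcripts alike, but the mitochondrial median lay 2.53 above the plastid median in wild type and 2.77 above it in the knockout. A change carried by 1 of the sets of arrays would be absent from the other, but the smallest median over sets and genotypes was 1.96. These values argue against all 3. A heat effect on mitochondrial transcript levels, or on how mitochondrial RNA is labelled (such as more polyadenylated RNA), may account for it, and these were not tested and stay open as hypotheses.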
